A study of Mus musculus with 8 samples.

How the data were processed

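The deposited file of each section lists molecules with their x, y and z position and a target name, and per the labels it comes from Resolve single-molecule fluorescence in situ hybridization. The unit used here is therefore the molecule, as called by the authors. Per the labels, GL261 glioma was grown in mouse brain, treatment was intracranial and hemispheres were taken at day 21. The submitters' processing notes name Seurat 4.2.0 without stating its role. Spot calling, image registration and their settings are not given in the sources used here. The pixel size is not given either, so distances are in pixels. Section thickness, section level and the number of animals are not given. The 28 targets named FP were read as false-positive codes, which the sources do not state, and were left out of gene values.

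Molecules were tallied per target and per square bin of 360 pixels (180 and 720 as alternatives). A bin counted as tissue with at least 20 molecules (50 as an alternative). The plan, written before the data were examined, compared the tumour territory and the surrounding tissue by marker lists. Of its tumour list only Mki67 and Birc5 are measured, and no gene of its neuron, oligodendrocyte and astrocyte lists is, so by the plan's own fallback the whole section became the main measure. After the data were examined, bins were classed as low-proliferation (under 10 molecules of Mki67 and Birc5), intermediate (10 to 99) and dense (100 or more), with 5 and 20 and with 50 and 200 as alternative limits. Zones were set by distance from the dense edge at 4 or more bins inside, 1 to 3 inside, and 1 to 3, 4 to 9 and 10 or more bins outside. Zones and the comparison of dense with low-proliferation bins used the 4 sections without CpG-STAT3ASO. The comparison of the margin with distant tissue used bins 1 to 3 and at least 10 bins outside.

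Gene values were log2 of CPM (molecules scaled to a total of 1e6 per section) plus 1 (10 as an alternative), for genes with a mean of at least 10 molecules per section (50 as an alternative). They were fitted by limma lmFit and eBayes with a trend, with 4 group means and contrasts for each comparison, the average effects of CpG-STAT3ASO and anti-PD1 and their interaction. Comparisons of bins within sections used a model with the section as block. Adjusted p values are Benjamini-Hochberg values with a threshold of 0.05, and all tests were two-sided. Scalings other than the share of molecules were molecules per bin and median-of-ratios size factors. Other fits were limma's voom, eBayes without trend, a fit with 2 groups and a fit with the replicate number as block. Shares of bins and densities were compared by exact permutation of sections, with a smallest p of 0.0286 for 4 against 4, 0.0571 for 3 against 4 and 0.333 for 2 against 2.

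Gene lists for T cells, cytotoxic and NK cells, checkpoints, homeostatic and activated microglia, monocytes and macrophages, suppressive myeloid cells, dendritic cells, neutrophils, interferon response, antigen presentation, STAT3 targets, TLR and NF-kB inflammation, chemokines, tumour, hypoxia and brain cell types were fixed before the data were examined. Of 21 lists with 308 genes, 71 genes are on the panel and 12 lists had at least 3 measured members. They were tested with limma's fry, and with camera at a preset correlation of 0.01 and at an estimated one. A member's call was also computed with adjustment over the list alone. Named genes follow a rule fixed before the data were examined. It takes, per contrast, up to 12 genes each way with the largest change among those past the threshold whose 2 sides do not overlap in any section. It adds a set list (Stat3, Tlr9, Pdcd1, Cd274, Cd8a, Cd4, Tmem119 and Mki67, as far as measured) and the 3 measured members of each list with the highest mean. Not every gene that the rule takes is printed. Other genes named in the text were chosen after their values were seen. A gene was taken to be at the false-positive level when its molecules did not exceed the 90th percentile of the false-positive codes.

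For the surroundings of T cell molecules, molecules within 100 pixels of an anchor (50 and 200 as alternatives) were compared with a ring of 400 to 600 pixels as a log2 density ratio with 0.5 added. The planned anchors were Cd3d, Cd8a and Cd4, and the sets without Cd4 and with Cd4 alone were added after the data were examined. The planned set is called T cell molecules below, although most of it was Cd4, which need not mark T cells here. Regions came from k-means with 8 clusters on 2155 bins drawn from each section. In 20 simulated runs, drawn from each gene's mean and its spread within groups, changes were put into 21 genes. They were recovered for the average effect of CpG-STAT3ASO in 17.1% of cases at 2-fold, 80% at 4-fold and 97.1% at 8-fold. In low-proliferation tissue these values were 22.4, 73.3 and 94.9%. For CpG-STAT3ASO against PBS they were 9.29, 39.3 and 72.9%, and for anti-PD1 against PBS in dense bins 6.43, 35.3 and 63.6%. For dense against low-proliferation bins they were 40.7, 82.9 and 93.4%, with 4.55 unchanged genes called per run. All simulated changes were given to randomly drawn genes with random signs. No joint fall of abundant genes was simulated, so these rates do not cover the shift in composition between sections with and without CpG-STAT3ASO. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, R 4.3.3 and limma 3.58.1 were used.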

Results

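Single-molecule transcript positions for a panel of 100 genes were examined in 8 sections of mouse brain hemisphere carrying GL261 glioma. Mice had received PBS, anti-PD1, CpG-STAT3ASO or both agents (the combination), with 2 sections per treatment. A section held 1669939 to 6995401 molecules, of which 0.106 to 0.306% carried a false-positive code. The labels do not state that the sections come from separate animals, so each p value measures only the spread between these sections.

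Mki67 and Birc5, a proliferation marker and the mitotic survival factor survivin, were dense over a large part of every section without CpG-STAT3ASO. Square bins with at least 100 molecules of these 2 genes, called dense here, made up 32.2 and 44.8% of the tissue bins with PBS and 37.2 and 46.2% with anti-PD1. They made up 0.983 and 1.5% with CpG-STAT3ASO and 1.01 and 3.24% with the combination. The mean was 1.68 ± 1.07% in the sections given CpG-STAT3ASO and 40.1 ± 6.61% in the others (SD, n = 4 each; difference -38.4 points, exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). Sections with and without anti-PD1 did not separate (difference 2.06 points, exact permutation p = 0.714). Bins with 10 to 99 molecules of the 2 genes, called intermediate, made up 28.7 ± 12.7% with CpG-STAT3ASO and 10.7 ± 3.15% without (exact permutation p = 0.0286). They reached 45.9% in combination replicate 2, against 15.4% in replicate 1. The low, intermediate and dense classes and the distance zones used below were defined after the data were examined.

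**Figure D1:**
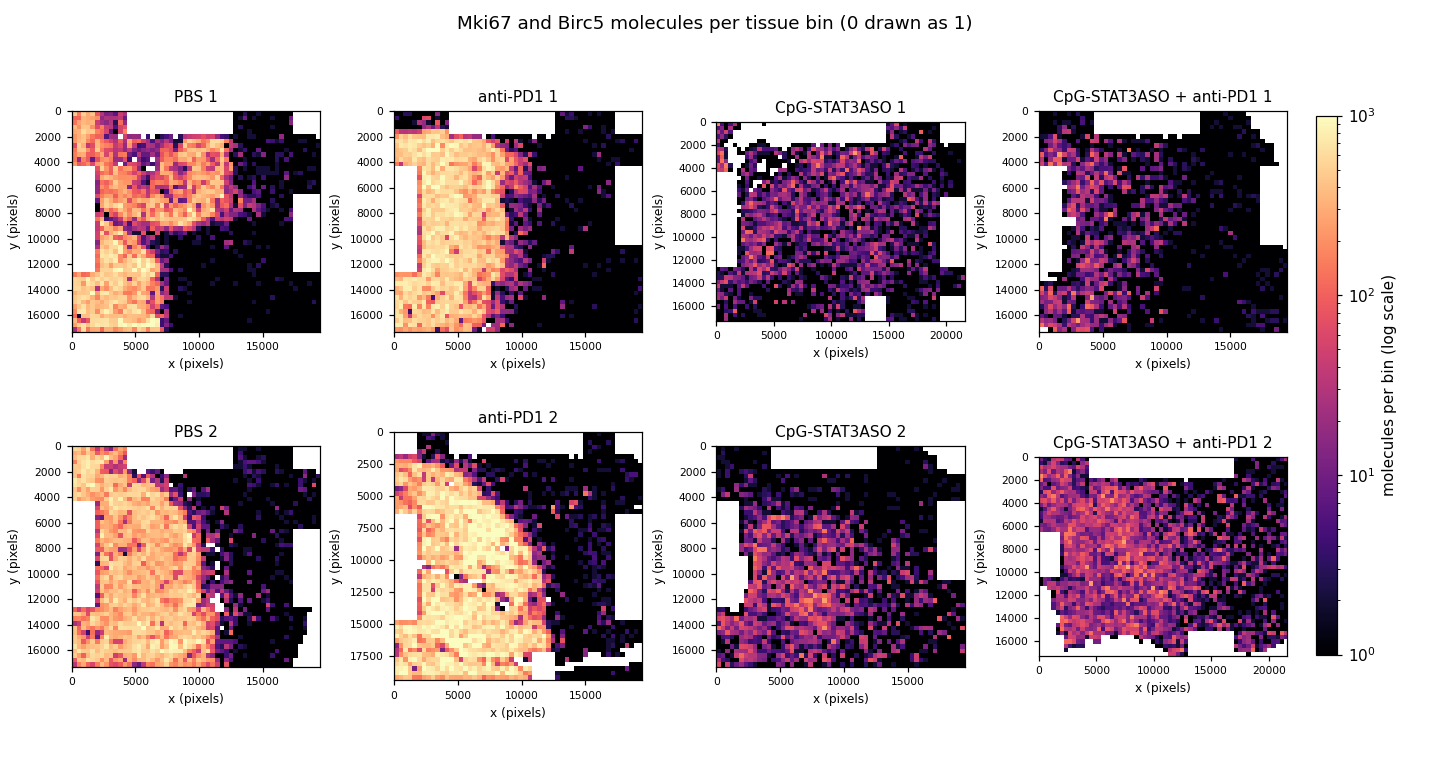
Sum of Mki67 and Birc5 molecules in each tissue bin of the 8 sections, on a log colour scale with 0 drawn as 1. Both spatial axes are in pixels.

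**Figure D2:**
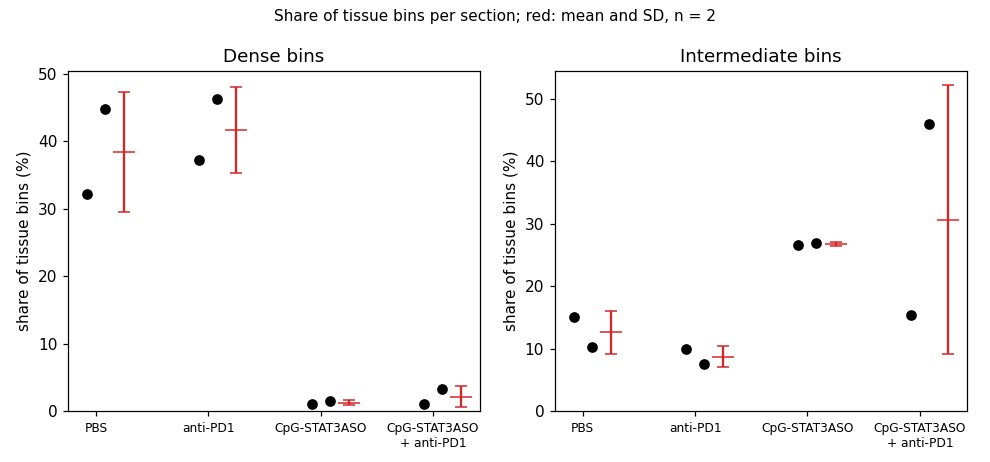
Share of tissue bins in the dense class and in the intermediate class for each section. Points are sections, and red marks are the mean and SD of each treatment (n = 2).

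Stat3, the transcript targeted by CpG-STAT3ASO, had 56440 and 61480 CPM (molecules scaled to a common total per section) with PBS and 55400 and 68370 with anti-PD1. It had 35090 and 39600 CPM with CpG-STAT3ASO and 42710 and 29710 with the combination. All 4 sections given CpG-STAT3ASO thus lay below all 4 others (36780 ± 5650 against 60420 ± 5930 CPM, SD, n = 4). The difference did not pass by share of molecules (log2 -0.72, SE 0.424, adjusted p = 0.189), and did per tissue bin (-2.14, adjusted p = 0.00509) and by median-of-ratios scaling (-1.41, adjusted p = 0.0282). In the bins with fewer than 10 Mki67 and Birc5 molecules, called low-proliferation, Stat3 differed by -0.22 by share (adjusted p = 0.647) and by 0.08 per bin (adjusted p = 0.868). Dense bins of the sections without CpG-STAT3ASO held 347 Stat3 molecules per bin, against 31.5 in low-proliferation bins. Per bin this was a log2 difference of 3.45, where the median of all genes was 3.1. By share of molecules it was 0.46.

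Across whole sections, CpG-STAT3ASO averaged over anti-PD1 changed 43 of 100 genes, with 35 higher and 8 lower. The 8 genes that fell were led by Gpnmb, which encodes a transmembrane glycoprotein (95010 ± 35100 to 10070 ± 3790 CPM, 9.47-fold, log2 -3.24, SE 0.444, adjusted p = 2.68e-05). Birc5 fell 8.19-fold (log2 -3.03, SE 0.335, adjusted p = 2.73e-06) and Mki67 5.38-fold (-2.43, SE 0.377, adjusted p = 9.25e-05). Cxcl10, an interferon-induced chemokine that draws T cells, went from 60910 to 12360 CPM (-2.59, SE 0.575, adjusted p = 0.00189). Smaller falls were seen for Tnfrsf9, which encodes the costimulatory receptor 4-1BB (-1.34), the stem cell antigen gene Ly6a (-1.21), the ribonucleotide reductase subunit gene Rrm2 (-1.05) and the CD11c gene Itgax (-0.95). Apart from Mki67 and Birc5, which define the bin classes, all 6 held a larger share of the molecules in dense than in low-proliferation bins of the sections without CpG-STAT3ASO, from 1.36 for Ly6a to 5.87 for Gpnmb on the log2 scale.

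Adgre1, which encodes the macrophage surface receptor F4/80, had the largest rise. It went from 738 ± 240 to 8126 ± 2320 CPM (11.1-fold, log2 3.47, SE 0.360, adjusted p = 2.18e-06). Cd68, a lysosomal glycoprotein gene of phagocytes, rose 6.10-fold (2.61, SE 0.380, adjusted p = 4.92e-05), and Csf1r, the receptor on which microglia depend, rose 4.15-fold (2.05, SE 0.385). Tlr9, the endosomal receptor for CpG DNA, went from 590 ± 200 to 2672 ± 488 CPM (2.22, SE 0.398, adjusted p = 0.000383). Msr1, a scavenger receptor gene, rose by 1.18 and Spp1, which encodes osteopontin, by 1.83. Tmem119, a marker of resident microglia, stood at -0.27 (adjusted p = 0.626). In the sections without CpG-STAT3ASO it held 73.3 molecules per dense bin against 5.88 per low-proliferation bin. Its molecules there ran from 18158 in PBS replicate 1 to 124196 in anti-PD1 replicate 2. Its value therefore cannot be assigned to resident microglia alone.

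The chemokine gene Ccl5 went from 2390 ± 1100 to 23640 ± 11100 CPM (10.2-fold, log2 3.35, SE 0.428, adjusted p = 1.44e-05). Il12b, the p40 subunit of IL-12 and IL-23, rose by 2.75 (SE 0.602), Ccl22 by 2.45 (SE 0.635), Ccl3 by 2.31 (SE 0.397), Il12a by 1.93, Tnf by 1.70, Il6 by 1.46 and Ccl4 by 1.31. Il12b, Il6 and Ifna2 did not exceed the false-positive level in any section without CpG-STAT3ASO, and Ccl22 and Tox exceeded it in 2 of these 4, so their folds start from that level. The costimulatory ligand genes Cd80 (2.12, SE 0.472) and Cd86 (1.62, SE 0.385) also rose. Both had a lower share in dense than in low-proliferation bins of the sections without CpG-STAT3ASO (-1.25 and -1.43). Neither was called in low-proliferation tissue. There Cd80 and Cd86 stood at 0.82 and 0.15 with CpG-STAT3ASO against PBS, and at 0.81 and 0.28 with the combination against PBS. Of the lymphocyte genes, Cd8a rose 3.20-fold by share (1.68, SE 0.506, adjusted p = 0.0137), Lag3 by 1.60, Tox by 2.17 and Cd4 by 1.97 (SE 0.477, adjusted p = 0.00309). Cd8a was not among the genes called in all 3 scalings given below. Its molecules numbered 1148 and 2651 with CpG-STAT3ASO, 1758 and 18335 with the combination and 1554 to 4032 in the other sections. Lag3, Tox and Cd4 had a lower share in dense bins, as given below, so their rises cannot be assigned to lymphocytes. Pdcd1, which encodes PD-1, stood at 0.84 (adjusted p = 0.185), Cd274, which encodes its ligand PD-L1, at 0.34 (adjusted p = 0.575), and Cd74, the MHC class II chaperone gene, at -1.38 (adjusted p = 0.101).

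Several of the genes that rose were also those with the lowest share in dense bins of the sections without CpG-STAT3ASO. Sirpa, the receptor for Cd47, rose by 1.98 with CpG-STAT3ASO and was lower by 5.55 on the log2 scale in dense than in low-proliferation bins. The corresponding pairs were 1.92 and 5.05 for the sphingosine receptor gene S1pr1, 1.97 and 5.92 for Cd4, and 2.26 and 3.78 for Fabp5, a fatty acid-binding protein gene. They were 2.48 and 4.54 for Flt3, 2.17 and 5.49 for Tox, 1.60 and 3.18 for Lag3, 1.93 and 4.30 for Il12a, 2.05 and 2.60 for Csf1r, and 1.12 and 2.47 for Crbn. Within low-proliferation tissue none of these 10 genes passed with CpG-STAT3ASO. Sirpa stood there at -0.42, Cd4 at -0.36, Crbn at -0.35, S1pr1 at -0.34, Lag3 at -0.28, Tox at -0.16, Il12a at -0.077, Fabp5 at 0.061, Csf1r at 0.17 and Flt3 at 0.41.

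The median change of all genes was 0.63 by share, -0.77 per tissue bin and -0.044 by median-of-ratios scaling. Of the called genes, 81.4% were higher by share, 6.45% of 31 per tissue bin and 52.9% of 34 by median-of-ratios scaling. Adgre1 and Cd68 rose in all 3 scalings (by 2.79 and 1.93 relative to the median gene), and all 8 genes that fell also fell in all 3. In all, 10 of the 43 were called in all 3 scalings, 38 kept their direction and 5 had the other sign per tissue bin without passing there (Ikzf2 -0.30, Crbn -0.29, Msr1 -0.23, Ccl4 -0.094 and Ifna2 -0.013).

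**Figure D3:**
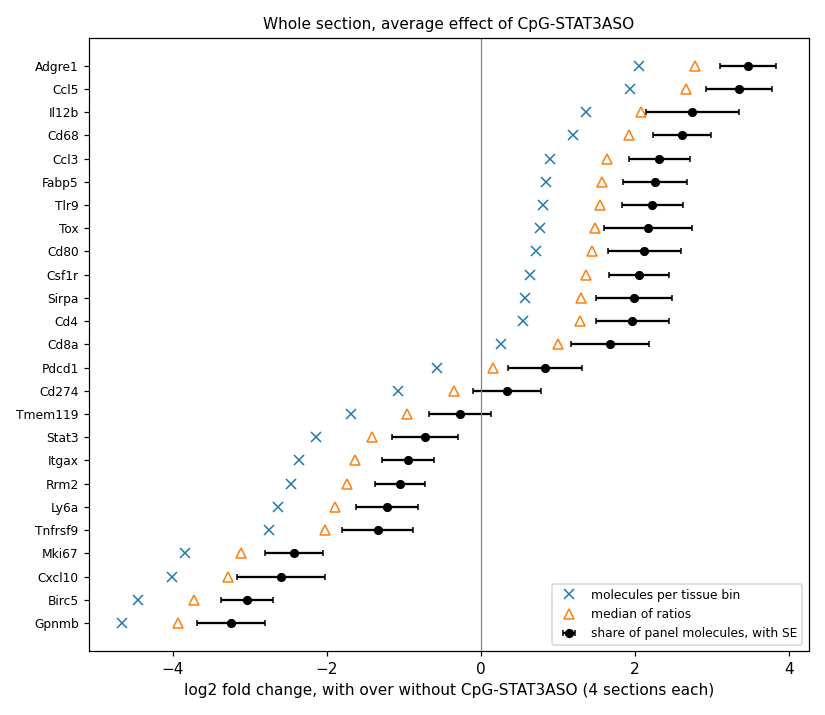
Log2 fold change with CpG-STAT3ASO in whole sections for the named genes, by share of molecules, per tissue bin and by median-of-ratios scaling. Bars are the SE of the share values (4 sections with and 4 without).

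Of 12 gene lists fixed before the data were examined with at least 3 measured members, limma's fry called 6 across whole sections. Each of these 6 calls was lost with an estimated correlation (adjusted p = 0.86). The count was 0 per tissue bin and 0 without PBS replicate 1 or 2, CpG-STAT3ASO replicate 1 or 2 or combination replicate 1 or 2, and 4 without either anti-PD1 section. Among TLR and NF-kB genes, 5 of 8 rose (Tlr9, Il12b, Tnf), none fell and 3 did not pass, with 5 adjusted over the list alone (adjusted p = 0.0255). Nfkbia stood at -0.09 and Il1b at -0.94. For antigen presentation 2 of 4 rose (Cd80, Cd86) and 2 did not pass (Cd74, and Cd40 at 0.19), with 2 adjusted over the list alone (adjusted p = 0.0255). Cd80 and Cd86 had a lower share in dense bins and were not called in low-proliferation tissue. For monocytes and macrophages 3 of 6 rose (Adgre1, Cd68, Ccr2) and 3 did not pass, with 3 adjusted over the list alone (adjusted p = 0.03), and Tgfbi stood at 0.48. For chemokines and their receptors 5 of 8 rose (Ccl5, Ccl3, Ccl22), 1 fell (Cxcl10) and 2 did not pass, among them Cxcl9 at -0.61, with 5 and 1 adjusted over the list alone (adjusted p = 0.03). For checkpoints 3 of 9 rose (Havcr2, Lag3, Tox), 1 fell (Tnfrsf9) and 5 did not pass, with 3 and 1 adjusted over the list alone (adjusted p = 0.036). Of these 3, Lag3 and Tox had a lower share in dense bins and did not rise in low-proliferation tissue, where Havcr2 stood at 0.65 (adjusted p = 0.217). For STAT3 and its targets 1 of 5 rose (Il6, at the false-positive level without CpG-STAT3ASO), 1 fell (Birc5) and 3 did not pass (Stat3, and Vegfa at 0.13 among them), with 1 and 1 adjusted over the list alone. That list was called lower (adjusted p = 0.0255) although its median was 0.017 and its mean -0.43.

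The other 6 lists were not called. Among activated microglia genes 4 of 6 rose (Cd68, Spp1, Ccl3, Ccl4) and 2 fell (Gpnmb, Itgax), with 4 and 2 adjusted over the list alone (fry adjusted p = 0.0783). Gpnmb and Itgax had a higher share in dense than in low-proliferation bins. Of 7 T cell genes 2 rose (Cd8a, Cd4) and 5 did not pass, with Il2ra at 0.10 and 2 adjusted over the list alone (adjusted p = 0.185). Cd4 had a lower share in dense bins and did not rise in low-proliferation tissue. Of 9 cytotoxic and NK genes 1 rose (Tbx21, at the false-positive level) and 8 did not pass, none adjusted over the list alone (adjusted p = 0.672). Nkg7 stood at 0.35, Fasl at 0.85 and Gzmb at -0.59. Of 6 suppressive myeloid genes 1 rose (Msr1) and 5 did not pass, with Tgfb1 at 0.28 and none adjusted over the list alone (adjusted p = 0.199). Of 6 dendritic cell genes 1 rose (Flt3), 1 fell (Itgax) and 4 did not pass, with 1 and 1 adjusted over the list alone (adjusted p = 0.188), Irf8 at -0.21 and Batf3 at 0.45. Of 4 interferon genes Cxcl10 fell and 3 did not pass, with 1 adjusted over the list alone (adjusted p = 0.38). Ly6g, the only neutrophil gene, stood at 0.64.

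CpG-STAT3ASO alone changed 25 genes against PBS, with 21 higher and 4 lower. Adgre1 rose by 3.30 (SE 0.509, adjusted p = 0.000509), Il12b by 3.17, Ccl22 by 3.02, Ccl5 by 2.96, Flt3 by 2.65, Il12a by 2.56, Fabp5 by 2.53, Ccr2 by 2.43, Tlr9 by 2.31, Tox by 2.25, Cd80 by 2.24 and Cd4 by 2.24. Gpnmb stood at -3.31, Cxcl10 at -2.86, Birc5 at -2.78 and Mki67 at -2.09, all 4 past the test. Stat3 differed by -0.66 (adjusted p = 0.444), Cd8a by 1.36 (adjusted p = 0.185), Pdcd1 by 0.18, Cd274 by 0.21 and Tmem119 by 0.46, none past the test. Per tissue bin 12 genes passed with 1 higher, and by median-of-ratios scaling 13 with 5 higher (median changes 0.63 by share, -0.83 and -0.032). The count was 5 without PBS replicate 2, 6 without CpG-STAT3ASO replicate 1 and 10 without CpG-STAT3ASO replicate 2.

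The combination changed 18 genes against PBS, with 14 higher and 4 lower. Adgre1 rose by 3.21 (SE 0.509, adjusted p = 0.000422), Ccl5 by 2.99, Cd68 by 2.76, Cd8a by 2.72 (SE 0.715, adjusted p = 0.0173), Il12b by 2.53, Tlr9 by 2.39, Cd80 by 2.18, Fabp5 by 2.13, Ccl3 by 1.96, Csf1r by 1.93, Havcr2 by 1.85 and Csf2rb by 1.68. Gpnmb stood at -2.96, Birc5 at -2.95, Cxcl10 at -2.94 and Mki67 at -2.32, all past the test. Cd8a had 1056 and 4674 CPM in the 2 combination sections, and its call was lost without replicate 2 (1.64, adjusted p = 0.118) and without PBS replicate 2 (2.12, adjusted p = 0.146), as it was per tissue bin (1.57, adjusted p = 0.381) and by median-of-ratios scaling (2.04, adjusted p = 0.0661). Stat3 (-0.73), Cd4 (1.91, adjusted p = 0.0514), Pdcd1 (1.04), Cd274 (0.54) and Tmem119 (0.17) did not pass. Per tissue bin 4 genes passed with 1 higher, and by median-of-ratios scaling 11 with 4 higher (median changes 0.58 by share, -0.56 and -0.094). The count was 6 without PBS replicate 2, 11 without combination replicate 1 and 31 without combination replicate 2.

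Set against anti-PD1, the combination changed 28 genes, 23 higher and 5 lower. Ccl5 rose by 3.73 (SE 0.606, adjusted p = 0.000315), Adgre1 by 3.64, Cd68 by 3.0, Spp1 by 2.97, Ccl3 by 2.58, Il12b by 2.33, Flt3 by 2.30, Tnf by 2.26, Lag3 by 2.25, Tlr9 by 2.14, Cd80 by 2.0 and Csf1r by 2.0. Cd8a rose by 1.99 (adjusted p = 0.0462) and Arg1, the arginase gene of suppressive myeloid cells, by 1.91 (adjusted p = 0.0344). Cd8a molecules numbered 1758 and 18335 in the combination sections and 4032 and 3258 with anti-PD1. The size of its rise thus rests largely on combination replicate 2. Birc5 stood at -3.29, Gpnmb at -3.18, Mki67 at -2.77, Cxcl10 at -2.33 and Rrm2 at -1.58, all past the test, and Stat3 at -0.79 (adjusted p = 0.36). Per tissue bin 14 genes passed with 2 higher, and by median-of-ratios scaling 13 with 5 higher (median changes 0.58 by share, -0.76 and -0.11). The count was 15 without anti-PD1 replicate 1, 9 without anti-PD1 replicate 2, 18 without either CpG-STAT3ASO section and 14 without combination replicate 1.

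Anti-PD1 averaged over CpG-STAT3ASO changed no gene by limma or voom, with 1 at unadjusted p under 0.05 (Ifnb1 at 1.56, adjusted p = 0.149). Cd8a stood at 1.04 (SE 0.506, adjusted p = 0.998), Pdcd1 at 0.20, Cd274 at 0.20, Mki67 at 0.11 and Tmem119 at 0.44. Without combination replicate 2 the count was 1. Anti-PD1 against PBS changed only Ifnb1, the interferon beta gene (1.34 to 13.1 CPM, log2 2.54, SE 0.586, adjusted p = 0.0426). Its count was at the level of the false-positive codes in every section, so a fit of genes above that level leaves it out and does not test it. At unadjusted p under 0.05 there were 3 genes in all, with Arg1 at -1.54 and Spp1 at -1.53 (adjusted p = 0.975 each).

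The combination against CpG-STAT3ASO changed no gene by limma or voom, with 2 at unadjusted p under 0.05, among them Arg1 (1.86, SE 0.610, adjusted p = 0.712). Cd8a stood at 1.36 (SE 0.715), Pdcd1 at 0.85, Cd274 at 0.33 and Stat3 at -0.066. The interaction of the 2 agents also gave none by limma or voom, with 3 at unadjusted p under 0.05. Arg1 was nearest, at 1383 CPM with PBS, 473 with anti-PD1, 531 with CpG-STAT3ASO and 1839 with the combination (interaction log2 3.40, SE 0.862, adjusted p = 0.102). Spp1 stood at 2.28 and Ifnb1 at -1.97 in the same test (adjusted p = 0.955 each). Without single sections the interaction count was 1 (PBS replicate 2), 1 (combination replicate 1) and 2 (combination replicate 2).

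In low-proliferation tissue, CpG-STAT3ASO averaged over anti-PD1 raised 9 of 98 genes, and none fell. Ccl5 went from 2353 ± 2520 to 17940 ± 8320 CPM (10.3-fold, log2 3.37, SE 0.523, adjusted p = 0.00416), and Msr1 from 131 to 993 (7.14-fold, 2.84, SE 0.415, adjusted p = 0.00416). Tgfbi, an extracellular matrix protein gene induced by TGF-beta, rose 4.28-fold (2.10, SE 0.381, adjusted p = 0.00699) and Adgre1 3.92-fold (1.97, SE 0.343, adjusted p = 0.0067). Ccl22 rose by 2.24, Ccl3 by 1.67, Csf2rb, a cytokine receptor subunit gene, by 1.34, and Ptprc, which encodes CD45, by 1.27. Gpnmb rose by 1.75 (1912 ± 717 to 6692 ± 3070 CPM, adjusted p = 0.0253), against its fall across whole sections. Just outside the test were Cd68 (1.14, adjusted p = 0.0527), Tlr9 (1.12, adjusted p = 0.0556), Cd8a (1.49, adjusted p = 0.0696) and Il12b (2.30, adjusted p = 0.0718). Pdcd1 stood at 0.96, Cd274 at 1.07 and Tmem119 at 0.00. Against PBS, Cd8a stood at 0.43 with CpG-STAT3ASO alone (adjusted p = 0.967) and at 1.785 with the combination (adjusted p = 0.287). Combination replicate 2 held 7.24 times the Cd8a of replicate 1 in these bins.

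The median change in this tissue was 0.41 by share, 0.72 per bin and -0.022 by median-of-ratios scaling, under which 9, 16 and 3 genes were called. Adgre1, Ccl5 and Msr1 passed in all 3 scalings. Without single sections the count was 3 (CpG-STAT3ASO replicate 1), 5 (anti-PD1 replicate 2) and 20 (combination replicate 1), and in bins far from proliferating tissue none of the 9 was called (adjusted p from 0.0841 to 0.885).

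In this tissue 4 of the 12 lists were called, each with fry adjusted p = 0.0448. Of 6 activated microglia genes 2 rose (Gpnmb, Ccl3) and 4 did not pass, with 5 adjusted over the list alone. Gpnmb held 602 molecules per dense bin against 1.30 per low-proliferation bin in the sections without CpG-STAT3ASO. Its rise therefore cannot be assigned to microglia. Of 6 monocyte and macrophage genes 2 rose (Adgre1, Tgfbi) and 4 did not pass, with 4 adjusted over the list alone. Of 8 chemokine and receptor genes 3 rose (Ccl5, Ccl22, Ccl3) and 5 did not pass, with 5 adjusted over the list alone. Of 6 suppressive myeloid genes 1 rose (Msr1) and 5 did not pass, with 2 adjusted over the list alone. All 4 calls were lost with an estimated correlation (adjusted p = 0.895 for the suppressive genes and adjusted p = 0.805 for the others). The count was 3 without CpG-STAT3ASO replicate 2 and 0 without any other single section.

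In the same tissue the combination against anti-PD1 raised 10 genes and lowered none. Ccl5 rose by 4.31 (SE 0.740, adjusted p = 0.0135), Msr1 by 3.25 (SE 0.587), Ifng, the interferon gamma gene, by 3.23 (SE 0.878), Cd8a by 2.56 (SE 0.653) and Pdcd1 by 2.09 (SE 0.527, adjusted p = 0.0476). Adgre1 rose by 2.28, Tgfbi by 2.19, Gpnmb by 2.11, Ccl3 by 1.87 and Csf2rb by 1.71. Across whole sections, combination replicates 1 and 2 held 119 and 1576 Ifng molecules, and 1011 and 4136 Pdcd1 molecules. In low-proliferation tissue, Ifng and Pdcd1 stood at 1.53 and 0.89 with the combination against PBS (adjusted p = 0.595 each). With anti-PD1 against PBS they stood there at -1.70 and -1.19. Low-proliferation bins of the sections without CpG-STAT3ASO held only 0.0224 Ifng molecules per bin. Cd8a was counted at 851 and 3401 CPM in the combination sections and at 346 and 240 in the anti-PD1 sections, and without combination replicate 2 it stood at 1.56 (adjusted p = 0.137). The median change was 0.63 by share, 1.12 per bin and 0.029 by median-of-ratios scaling, under which 10, 14 and 0 genes passed. Leaving out single sections gave 0 (anti-PD1 replicate 2), 3 (anti-PD1 replicate 1 or either CpG-STAT3ASO section), 5 (combination replicate 2) and 16 (combination replicate 1).

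The other contrasts in low-proliferation tissue gave few or no calls by limma. The combination raised Msr1 against PBS (3.20, SE 0.587, adjusted p = 0.0297), with 12 genes at unadjusted p under 0.05. Per bin 4 genes passed, and by median-of-ratios scaling none (Msr1 adjusted p = 0.0594; median changes 0.17 by share, 0.62 and -0.087). CpG-STAT3ASO alone against PBS gave none, with 8 at unadjusted p under 0.05, and anti-PD1 against PBS none, with 3 (Ccl5 at -1.80, Pdcd1 at -1.19 and Lag3 at -1.02). The combination against CpG-STAT3ASO and the average of anti-PD1 gave none, also at unadjusted p under 0.05. The latter had a median change of -0.17, and its count was also 0 by voom and 1 without combination replicate 2. The interaction gave none, with 5 at unadjusted p under 0.05, among them Pdcd1 at 2.25 and Cd8a at 2.13 (adjusted p = 0.877 each).

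**Figure D4:**
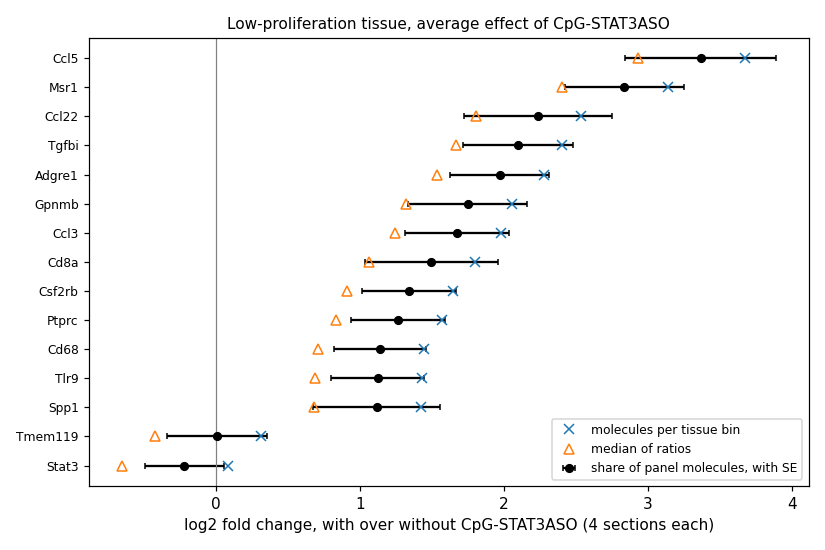
Log2 fold change with CpG-STAT3ASO in low-proliferation tissue for the 9 called genes and 6 others, by share of molecules, per bin and by median-of-ratios scaling. Bars are the SE of the share values (4 sections with and 4 without).

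Dense and low-proliferation bins differed in 55 of 98 genes within the 4 sections without CpG-STAT3ASO, 28 higher and 27 lower in dense bins (median change of all genes 0.17 by share). Of the genes higher in dense bins, apart from the 2 that define the classes, Gpnmb showed the largest contrast, at 602 ± 154 molecules per dense bin against 1.30 per low-proliferation bin (log2 5.87 by share, SE 0.232, adjusted p = 6.3e-06, n = 4 sections). Cxcl10 was higher by 3.24 (398 against 7.39 per bin), Ifng by 2.85, Msr1 by 2.56, Tgfbi by 2.35, Cxcl9 by 2.25 and Cd74 by 2.20 (1380 against 48.0 per bin). Itgax and Tnfrsf9 were each higher by 2.0, Il1b by 1.98, Arg1 by 1.91, the granzyme genes Gzmc and Gzmb by 1.72 and 1.30, and Nkg7, a cytotoxic granule gene, by 1.55. Gzmc exceeded the false-positive level in 2 of these 4 sections. It had 2332 molecules in PBS replicate 2, against 239 in PBS replicate 1 and 373 and 368 with anti-PD1. Irf8 was higher by 1.24, Cd274 by 1.01 and Stat3 by 0.46 (SE 0.127, adjusted p = 0.0201).

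Cd4 (-5.92), Sirpa (-5.55), Tox (-5.49), S1pr1 (-5.05), Flt3 (-4.54), Il12a (-4.30), Fabp5 (-3.78) and Lag3 (-3.18) were the genes with the lowest share in dense bins. Cd4 was counted at 2.75 molecules per dense bin and 21.7 per low-proliferation bin, and Sirpa at 24.9 against 144. Csf1r was lower by share (-2.60) but stood at 0.38 per bin (adjusted p = 0.202). Adgre1 (-1.63) and Cd68 (-1.47) were lower by share and higher per bin, at 2.95 against 1.18 and 12.8 against 4.30 molecules. Cd8a (0.03) and Tmem119 did not differ by share, the latter at 73.3 molecules per dense bin against 5.88. Per bin, 94 genes passed with 87 higher, around a median change of 3.1. Anti-PD1 against PBS changed no gene of dense bins by limma, with 4 at unadjusted p under 0.05 (Ifnb1, Arg1 at -1.65, Tmem119 at 1.56 and Spp1 at -1.56; median change of all genes 0.13), and the count was 2 without PBS replicate 2.

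Around the dense territory, bins 1 to 3 steps outside its edge differed from bins at least 10 steps away in 60 of 96 genes, 48 higher and 12 lower near the edge (median change of all genes 0.94 by share). Gpnmb was higher by 5.70 (28.3 against 0.397 molecules per bin) and Cxcl10 by 5.17 (63.5 ± 53.5 against 2.05, SE 0.482, adjusted p = 0.000114, n = 4). Of the cytotoxic and T cell genes, Nkg7 was higher by 3.67, Ifng by 3.59, Gzmb by 2.76, Il2ra by 2.49, Pdcd1 by 2.27, Foxp3 by 1.87 and Cd8a by 1.45 (SE 0.423, adjusted p = 0.0179). Others did not pass, among them Cd4 at -1.61 (adjusted p = 0.0628), Lag3 at -0.85, Icos at -0.24, Klrc1 at 1.31, Cd28 at 0.87 and Fasl at 0.77, and Tox was lower. No list was tested in this comparison. These bins also held more Mki67 (19.2 against 0.538 per bin, 4.72), Birc5 (3.20) and Rrm2 (2.44). Cxcl9 was higher by 3.47, Itgax by 3.26, Ccl5 by 3.24 (5.79 against 1.01 per bin), Tgfbi by 2.98, Cd74 by 2.81, Msr1 by 2.74, Il1b by 2.66, Arg1 by 2.55, Pdcd1lg2 by 2.52 and Cd274 by 1.90. Tox (-3.12), Flt3 (-2.57), Il12a (-2.57), Sirpa (-1.85), Crbn (-1.77) and S1pr1 (-1.36) were lower near the edge. Per bin 65 genes passed, 57 of them higher, and without PBS replicate 1 the count by share was 37.

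From at least 4 steps inside the territory to at least 10 outside, 5 zones gave Cd74 at 1543, 1354, 208, 67.4 and 27.6 molecules per bin. Cxcl10 went through 451, 387, 63.5, 9.30 and 2.05, and Cd8a through 2.09, 2.45, 0.876, 0.398 and 0.227. Ccl5 stood at 12.9, 12.7, 5.79, 2.18 and 1.01 and Tmem119 at 87.2, 69.2, 8.94, 6.68 and 4.85. Sirpa ran the other way, at 22.5, 25.7, 72.3, 134 and 166.

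**Figure D5:**
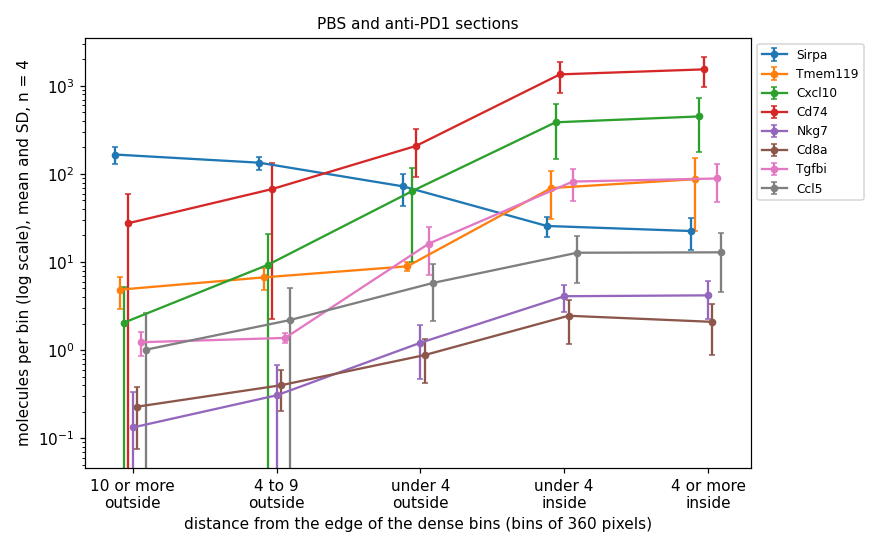
Molecules per bin of 8 genes in 5 zones by distance from the dense edge, on a log axis, in the sections without CpG-STAT3ASO. Points are means and bars the SD (n = 4); a bar that reaches the bottom runs to or below 0.

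The density of the T cell list inside over outside dense bins had a log2 ratio of 0.32 ± 0.515 with CpG-STAT3ASO and -0.67 ± 0.390 without, a difference of 0.98 (n = 4 each, exact permutation p = 0.0286). The sections given CpG-STAT3ASO held only 22 to 78 dense bins. Their ratios were 0.17 and 1.08 with CpG-STAT3ASO and 0.022 and -0.0093 with the combination, and their mean was 0.061 without CpG-STAT3ASO replicate 2. All 4 sections without CpG-STAT3ASO were below 0 (-1.20 and -0.29 with PBS, -0.50 and -0.67 with anti-PD1). Cd4, the most abundant member, lay mainly outside dense bins in the sections without CpG-STAT3ASO. With Cd3d and Cd8a alone, chosen after the data were examined, the ratio was 0.73 ± 1.93 with CpG-STAT3ASO and 2.33 ± 1.09 without (difference -1.59, exact permutation p = 0.257). It was -2.04 and 2.48 with CpG-STAT3ASO and 1.28 and 1.21 with the combination, and the difference was -0.67 without CpG-STAT3ASO replicate 1. The sections did not separate by anti-PD1 with the full list (exact permutation p = 0.686) or with Cd3d and Cd8a (exact permutation p = 0.371).

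Around molecules of Cd3d and Cd8a, 13 genes were over 2-fold denser in all 8 sections than in a ring farther away; no list was tested. Gzma was 11.3-fold denser (log2 3.50 ± 1.24, SD, n = 8), Nkg7 11.0-fold, the NK receptor genes Klrc1 10.8-fold and Klrd1 8.77-fold, Gzmb 9.86-fold, Pdcd1 7.56-fold, the death ligand gene Fasl 7.51-fold and Ifng 7.04-fold. Prf1, which encodes perforin, was 6.34-fold denser, Cd28 5.03-fold, Il2ra 4.31-fold, Ctla4 3.90-fold and Ptprc 3.48-fold. Ccl5 was 2.36-fold denser on average, not over 2-fold in every section, and Gzmc was denser in 7 of 8 sections (log2 1.65 ± 1.11). Cd3d exceeded the false-positive level in 5 of the 8 sections and Gzmc in 3. Cd274 was 1.24-fold denser and Tmem119 1.17-fold. This surrounding differed with CpG-STAT3ASO in 1 of 91 genes, Il16, a lymphocyte chemoattractant gene (0.98, SE 0.146, adjusted p = 0.0427), with 15 at unadjusted p under 0.05.

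With the planned anchors, most of which were Cd4 in every section (Cd3d and Cd8a made up 2348 of 36412 in PBS replicate 1 and 19033 of 53708 in combination replicate 2), 2 of 95 genes differed with CpG-STAT3ASO, Il10 (-0.91, SE 0.109, adjusted p = 0.0134) and Ccl4 (-1.10, SE 0.184, adjusted p = 0.0413), with 26 at unadjusted p under 0.05. Anti-PD1 changed none by limma around either set, with 0 (planned) and 5 (Cd3d and Cd8a) at unadjusted p under 0.05. With Cd4 anchors alone, chosen after the data were examined, 13 of 95 genes differed, all lower with CpG-STAT3ASO. Among them were Ifng (-1.73, adjusted p = 0.00157), Il2ra (-1.19) and Pdcd1 (-1.09). Cd4 itself was only 1.39-fold denser around Cd3d and Cd8a molecules. Its share in dense against low-proliferation bins stood at -5.92, beside Sirpa at -5.55. Cd4 anchors, alone or in the planned set, therefore cannot be taken to mark T cells. The planned count was 9 without PBS replicate 1 and 0 without PBS replicate 2, combination replicate 1 or either CpG-STAT3ASO section.

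Grouping bins of all sections by their transcripts gave 8 regions. Regions 5 (Cxcl10, Gpnmb, Mki67, Cd74) and 8 (Gpnmb, Mki67, Birc5, Rrm2) held 5333 and 4498 molecules per bin. Region 4 was led by Ccl5, Cxcl10, Cd74 and Cd274 and held 1529 per bin, and region 7 by Ccl5, Tgfbi, Spp1, Cd68 and Adgre1, with 1325. Regions 1 (Cd4, Sirpa, S1pr1), 2 (Cd4, Csf1r, Sirpa, Tmem119), 3 (Sirpa, Crbn) and 6 (Sirpa, S1pr1, Csf1r) held 689 to 879 molecules per bin.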

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

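The tests of molecule detection, of imaged depth, of bins next to proliferating tissue and of detection in combination replicate 1 were chosen after the results were seen. Of the codes outside the gene panel, FP 13 stood far above the others in every section. It was counted 3316 to 5348 times per section, where the median code had 9.5 to 60.5 molecules.

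The sections given CpG-STAT3ASO held little dense proliferative tissue (1.68 against 40.1% of tissue bins). Mki67 per tissue bin was 13.8-fold lower in these sections, while low-proliferation bins held 1.28 times as many molecules as in the others. Single sections held 635 to 1280 molecules per low-proliferation bin with CpG-STAT3ASO and 637 to 764 without. For 6 genes spread over the parenchyma the median ratio per such bin was 0.978 (0.901 to 1.08). Lower detection by the fold of Mki67 is thus argued against. These bins are themselves chosen by detected Mki67 and Birc5, so a smaller loss of detection is not excluded. Imaged depth differed by less than the fold of Mki67, with 1.43 times as many z planes in the sections without CpG-STAT3ASO. It still separated the sections fully, at 31 to 49 z planes without CpG-STAT3ASO and 23 to 30 with it. So did false-positive molecules per tissue bin (3.25 without against 2.22 with, exact permutation p = 0.0286). A difference in imaging between the 2 sets of sections therefore stays open. The placement of the imaged field stays open: the number of tissue bins differed by a ratio of 1.02, and no value in the files shows where the tumour lay outside the field. A smaller tumour with CpG-STAT3ASO therefore could not be told apart from a section cut away from it. The dense class rests on Mki67 and Birc5 alone, and Birc5 is also on the list of STAT3 and its targets. Its share therefore cannot tell the extent of tumour apart from the level of these transcripts within it.

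In low-proliferation tissue 9 genes were higher with CpG-STAT3ASO (median log2 1.97), among them Ccl5, Msr1, Adgre1, Gpnmb and Ptprc. Tumour transcripts scattered in these bins might account for part of this. Mki67 and Birc5, which define the bins, were left out of this test. The other 10 uncalled genes highest in dense over low-proliferation bins had a median change of 0.539 (SD 0.664). That was under the bound of 0.985 set before the test, by less than the SD of these genes; the condition on the SD was applied after the value was seen, and the explanation was left open. Closeness to proliferating tissue also stays open, because in bins far from it the 9 genes had a median change of 0.854 (SD 0.655, 0.222 to 2.47), neither above 0.985 nor near 0, and none of the 9 was called. A response of the surrounding tissue to CpG-STAT3ASO is the biological explanation that the design names, and it was not tested apart from these.

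Combination replicates 1 and 2 differed by a median of 0.861 on the log2 scale and by over 2-fold in 45 genes, where replicates of the other treatments differed by 0.488 to 0.595. In low-proliferation bins replicate 2 held 7.24 times the Cd8a of replicate 1, 12.5 times the Cd74, 10.5 times the Cd274 and 123 times the Cxcl9. Lower detection in replicate 1 is argued against by 6 genes spread over the parenchyma, whose median log2 ratio was -0.134 (-0.307 to 0.0376), against 2.86 for Cd8a. A difference between animals and a difference in section level stay open and were not tested.

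Other splits of the 8 sections into 4 and 4 were fitted with 2 groups. For CpG-STAT3ASO only 1 of 35 splits, the real one, called as many genes across whole sections (45 genes, highest other 3). That is the smallest share that 35 splits allow, so chance is made unlikely only to that extent and is not excluded. The same held in low-proliferation tissue (1 of 35; 15 genes, highest other 1) and for the surroundings of T cell molecules (1 of 35; 12 genes, highest other 5), where the fit with 4 groups called 2 genes, 0 when any 1 of 4 sections was left out, and 1 with Cd3d and Cd8a anchors. For anti-PD1 the real split called 0 genes across whole sections and in low-proliferation tissue, so all 35 of 35 splits had to call as many and the count says nothing about chance. The highest other splits (45 and 15 genes) were the split by CpG-STAT3ASO, a structure of the samples. For dense against low-proliferation bins (55 genes, highest other 0) and the margin against distant tissue (60 genes, highest other 0), 1 of 8 swaps gave as many, and 8 swaps are too few to exclude chance.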

How the results depend on the processing

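The restriction to genes above the false-positive codes, the bin classes with their limits, the far bins, the Cd3d and Cd8a anchors and the Cd4 anchors were chosen after seeing the data. Of 1984 alternative values of single genes, 1603 kept their side of the threshold, 368 lost the call and 13 gained it. No called gene among these reversed, and 16 values of uncalled genes changed sign. Among all genes called for CpG-STAT3ASO across whole sections, 5 had the other sign per tissue bin without passing (Ikzf2, Crbn, Msr1, Ccl4 and Ifna2). Uncalled genes of other comparisons changed sign too, such as Pdcd1 (-0.11), Cd274 (-0.61) and Tmem119 (-0.97) per tissue bin for the combination against PBS. The dense share kept its direction in every alternative (-34.3 to -41.3 points). The cause of a change below was not tested unless it is given. Scaling: per tissue bin, 0 genes were called for anti-PD1 against PBS (1 by share), 12 for CpG-STAT3ASO against PBS (25), 4 for the combination against PBS (18), 14 for the combination against anti-PD1 (28), 16 for CpG-STAT3ASO in low-proliferation tissue (9), 94 for dense against low-proliferation bins (55) and 1 for anti-PD1 in dense bins (0). By median-of-ratios scaling the counts were 13 for CpG-STAT3ASO against PBS, 11 for the combination against PBS, 13 for the combination against anti-PD1, 3 for CpG-STAT3ASO in low-proliferation tissue and 0 for the combination against anti-PD1 there (10). Fits: anti-PD1 against PBS gave 0 with pseudocount 10 and without trend. It also gave 0 with genes of mean 50 or more and with genes above the false-positive codes. These 2 filters leave out Ifnb1, its only called gene, so their count of 0 was fixed in advance. The combination against anti-PD1 in low-proliferation tissue gave 3 by voom, 4 without trend and 4 with bins of 180 pixels. CpG-STAT3ASO in that tissue gave 15 with a 2-group fit, 4 in core bins and 1 in far bins, both subsets of the low-proliferation bins. Lists: of 6 called across whole sections, camera called 0 with the preset correlation and 0 with an estimated one, fry called 0 per tissue bin and 2 by median-of-ratios scaling, and the combination against PBS had 1 by the latter (0). Of 4 in low-proliferation tissue, camera called 1 and 0, and fry 0 by median-of-ratios scaling. The surroundings of T cell molecules gave 6 genes at a radius of 50 pixels, 6 at 200, 1 with Cd3d and Cd8a anchors and 13 with Cd4 anchors (2). T cell density reversed with Cd3d and Cd8a only, at -1.59 (0.98). With the replicate number as block, the average of anti-PD1 called 1 gene (0), CpG-STAT3ASO 41 (43), and the combination against anti-PD1 in low-proliferation tissue 2 (10). The replicate numbers were not shown to pair sections, since the deviations of replicate 1 from its group mean correlated between groups at -0.525 to 0.589. Leaving out single sections leaves a group with 1 section, assumed to vary like the others. T cell density then ranged from 0.726 to 1.11 and the dense share from -41.0 to -36.4, with a smallest possible exact permutation p of 0.0571. Counts ranged from 30 to 47 for CpG-STAT3ASO across whole sections (43), 5 to 33 for CpG-STAT3ASO against PBS (5 without PBS replicate 2, 6 and 10 without CpG-STAT3ASO replicates 1 and 2), and 6 to 31 for the combination against PBS (6 without PBS replicate 2, 11 and 31 without combination replicates 1 and 2). They ranged from 9 to 34 for the combination against anti-PD1 (15 and 9 without anti-PD1 replicates 1 and 2, 18 without either CpG-STAT3ASO section, 14 without combination replicate 1), and 0 to 1 for anti-PD1 against PBS (0 without either anti-PD1 or either CpG-STAT3ASO section). The range was 0 to 1 for the average of anti-PD1 and for the combination against CpG-STAT3ASO (1 without combination replicate 2 in both), and 0 to 2 for the interaction (1 without PBS replicate 2 and combination replicate 1, 2 without combination replicate 2). In low-proliferation tissue it was 3 to 20 for CpG-STAT3ASO (5 without anti-PD1 replicate 2, 3 without CpG-STAT3ASO replicate 1, 20 without combination replicate 1), 0 to 1 for anti-PD1 (1 without combination replicate 2) and 0 to 16 for the combination against anti-PD1 (3 and 0 without anti-PD1 replicates 1 and 2, 3 without either CpG-STAT3ASO section, 16 and 5 without combination replicates 1 and 2). It was 0 to 2 for anti-PD1 in dense bins (2 without PBS replicate 2), 37 to 62 for the margin (37 without PBS replicate 1) and 0 to 9 for the surroundings of T cell molecules (9 without PBS replicate 1; 0 without PBS replicate 2, combination replicate 1 or either CpG-STAT3ASO section). Lists ranged from 0 to 4 across whole sections (0 without any section of PBS, CpG-STAT3ASO or the combination) and from 0 to 3 in low-proliferation tissue (0 in 7 of 8 cases). Territories with 6 or 12 clusters and a quality column were not run, since the territory could not be defined as planned and the files hold no such column, and T cell density with bins of 720 pixels gave no value because a section had no dense bins. Low counts limit the genes at the false-positive level: Icosl, Tbx21, Ifnb1, Il2, Ly6g and Xcr1 did not exceed it in any section, and 19 genes did not in at least 1.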

Other observations

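Replicates of a treatment other than the combination differed by over 2-fold in 24 to 27 genes, against 45 for the combination. Their correlations over all genes were 0.973 to 0.975, against 0.92 for the combination. The wide range of abundance between genes keeps these correlations high. The first principal component of the sections held 63.5% of the variance and the second 16.3%. Sections given CpG-STAT3ASO held 1053 molecules per tissue bin and the others 2704 (exact permutation p = 0.0286), and 887 ± 291 against 692 ± 64.0 per low-proliferation bin (exact permutation p = 0.343). They spanned 25.8 z planes against 36.8 (exact permutation p = 0.0286). Of the panel, 29 genes were in no list.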
